A study of Arabidopsis thaliana with 4 samples.

How the data were processed

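Leaf RNA of Arabidopsis thaliana Col-0 seedlings was measured on 4 Affymetrix ATH1 arrays, 2 from mock-treated and 2 from seedlings co-cultivated with Agrobacterium tumefaciens C58 for 8 h. Per the labels' protocols, plants were grown on solid medium to 3 weeks and moved to liquid medium, the inoculum was 5 µL at an OD600 of 1.5, and 500 ng of total RNA per sample was labelled with the Affymetrix 3' IVT Express kit. The treatment text of the mock samples is the same as that of the inoculated samples, so the groups were taken from the sample titles and source names. The titles, the tissue field and the series design name leaf, whereas the description field names roots; the samples were treated as leaf, and markers of both organs were read from the arrays.

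Per the submitters' processing notes, the values were made by RMA, which corrects background, quantile normalises probes and summarises each probe set. The deposited values are on the log2 scale, which the range of each array (4.48 to 14.23 over the 4 arrays) also shows. The software and version of RMA, and which arrays were normalised together, were not given in the sources used here. No raw intensities were analysed here. On an array the precision is limited by the number of arrays, here 2 per group.

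The deposited log2 values were used as they stand. Of 22810 probe sets, 64 control probe sets were kept apart and 22746 were tested. Names came from a probe table that lists 14016 probe sets, of which 13513 carry 1 gene and 503 several, and 8730 tested probe sets have no name in it. By Entrez gene ID, 13436 of the 1-gene probe sets matched the RefSeq annotation of TAIR10.1, and 11933 carry only a locus code as their symbol. Genes with a symbol of their own are thin in the table, since 1530 of 10492 such genes have a 1-gene probe set.

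Inoculated and mock leaf were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, group as the only term, 2 residual degrees of freedom). P-values are two-sided and Benjamini-Hochberg adjusted over all 22746 probe sets, and a probe set was called at an adjusted p under 0.05. The prior had 1.53 degrees of freedom and an SD of 0.148. These p-values measure the spread between these 4 arrays, part of which may be technical, and an exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333.

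Before the data were examined, 30 gene lists with 577 genes were fixed, together with the design, the rule for named genes and the other settings to try. Each gene was read from the 1-gene probe set with the highest mean over the 4 arrays. Of the 577 genes, 85 had such a probe set, which left 14 lists with at least 3 members, 11 with 1 or 2 and 5 with none. Lists of at least 3 were tested with limma's camera at a preset correlation of 0.01, adjusted over the 14 lists, with camera at an estimated correlation and fry beside it. Members were also adjusted over the list alone.

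The rule for named genes took up to 14 called 1-gene probe sets per direction whose groups do not overlap, filled by up to 6 with the smallest unadjusted p where fewer were called. It added the 4 members of each fixed list with the smallest p, the control probe sets, and 7 genes whatever their values (PR1, FRK1, PDF1.2a, VSP2, ARR5, IAA19 and CCA1), of which the probe table holds PDF1.2a alone.

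After the files were read and before the fit, 29 families were added by gene symbol or chromosome. After the fit had been seen, 5 genes were taken out of them because their symbol means another protein (2 peptide deformylases, 2 cyclophilins and 1 tRNA methyltransferase subunit), and 4 lists were added, 3 of them with at least 3 members. These 4 lists leave out the genes already seen in the ranking.

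Settings chosen before the data were examined were an intensity trend, a robust prior, minimum mean log2 values of 5 and 7, repeated quantile normalisation, median centring, cyclic loess, leaving out probe sets marked as cross-hybridising, a replicate block, leaving out each array, an adjusted p under 0.10 and a log2 difference of at least 1. Chosen after seeing the data were array weights, set to the inverse of each array's own variance from the differences between arrays, and averaging the 2 inoculated arrays into 1 sample.

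The fit was tested on simulated data with 22746 probe sets, 200 of them changed. With the noise of the real arrays it recovered 0% of changes of 1 log2, 20.9% of 2 and 69.7% of 4 with 0 false calls, and with array weights 92.5%, 100% and 100% with 9 false calls. With equal noise on every array it recovered 1.49%, 85.1% and 100% with 7 false calls. A list planted in data with the noise of the real arrays had a camera p of 1.74e-13 without weights, and 0 of the null lists had a p under 0.05. Noise was drawn independently for each probe set, so the simulation cannot show how camera does where list members are correlated. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.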

Results

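Transcript levels were read in leaves of Arabidopsis Col-0 seedlings 8 h after mock treatment (2 arrays) or inoculation with Agrobacterium tumefaciens C58 (2 arrays), a soil bacterium that moves DNA into plant cells and causes crown gall. Each array gave an RMA log2 value for 22746 plant probe sets, with medians of 6.40 and 6.29 in the mock and 6.37 and 6.36 in the inoculated arrays. The comparison asks how the leaf transcriptome responds to the bacterium.

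The transcripts that fell most in inoculated leaf included 2 related genes of the AZI1/EARLI1 family of lipid-transfer-like proteins. AT4G12500 went from a mean log2 value of 10.97 in mock to 5.65 in inoculated leaf, a difference of -5.32 ± 0.122 (SE, n = 2 arrays per group) or 40.1-fold lower, and AT4G12490 from 12.83 to 8.00, a difference of -4.83 ± 0.104 or 28.5-fold lower. AT2G43620, of the chitinase family, fell from 11.36 to 7.28 (-4.08 ± 0.102 SE, 17.0-fold lower). AT1G47400, an IRON MAN peptide of the iron deficiency response, fell from 9.92 to 5.83 (-4.09 ± 0.125 SE, 17.0-fold lower), and AT1G65500 fell from 9.88 to 6.71 (-3.17 ± 0.102 SE, 8.99-fold lower). The adjusted p was 0.0364 for AT4G12500, AT4G12490 and AT2G43620 and 0.0497 for AT1G47400 and AT1G65500. For all 5 genes both inoculated arrays lay below both mock arrays, which the rule for named genes required. The groups did not overlap in 49.8% of all probe sets. The 33.3% expected by chance holds only for arrays of equal spread. These were unequal, with own SDs of 0.140 and 0.650 in mock replicates 1 and 2 and 0.0620 in each inoculated array. The 49.8% is therefore no evidence of a broad response. The folds are ratios of RMA values; the inoculated levels of AT4G12500 and AT1G47400 were close to those of the low-reading root hair marker EXPA18 (5.61 and 5.66), and signal above background was not tested there, so the folds of these genes are not exact transcript ratios.

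In all, limma called 9 of 22746 probe sets, 1 higher and 8 lower in inoculated leaf, and 3002 had an unadjusted p under 0.05. The other 4 called probe sets have no gene in the probe table: 1 was higher by 3.16 and 3 were lower, with differences of -5.41, -4.53 and -3.74. The counts rested on single arrays: limma called 0 probe sets without inoculated replicate 1 (575 at an unadjusted p under 0.05) and 0 without inoculated replicate 2 (560), but 17356 without mock replicate 1 and 8358 without mock replicate 2, each with the lone array of a group assumed to vary like the other group. With array weights, chosen after seeing the data, 2783 were called (1357 higher, 1426 lower), and with the 2 inoculated arrays averaged into 1 sample, which keeps the differences and leaves 1 residual degree of freedom, 0 were (568 at an unadjusted p under 0.05). The weighted fit leaned on mock replicate 1 and on the closeness of the inoculated pair. Own variances were 0.0197 and 0.422 in mock replicates 1 and 2 and 0.00385 in each inoculated array. Beside the 1 higher and 8 lower as deposited, repeated quantile normalisation gave 16 higher and 29 lower and cyclic loess 66 higher and 88 lower. At an adjusted p under 0.10, 200 were higher and 234 lower.

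Next in order stood named genes with an adjusted p of 0.0511, which did not pass the test. Lower by value were the class III peroxidase gene AT5G64120 (-3.15 ± 0.106 SE), the protease inhibitor gene AT2G38870 (-2.80), the sulfur deficiency gene AT1G04770 (-2.51), the SABATH methyltransferase gene AT5G37970 (-2.50, to a low inoculated level of 4.90), the chitinase family gene AT2G43590 (-2.38) and the isoflavone reductase-like gene AT1G75280 (-2.14). Higher by value were the lipid-transfer-like gene AT1G62510 (3.28 ± 0.126 SE), MCCA (2.51), which encodes a subunit of 3-methylcrotonyl-CoA carboxylase in leucine breakdown, AT2G20670 (2.47), AT1G50040 (2.32), AT1G54740 (2.30) and the glycine-rich protein gene AT2G05540 (2.18). For all 12 genes both inoculated arrays lay on one side of both mock arrays (n = 2 arrays per group). The rule for named genes required this, so it adds no support.

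**Figure D1:**
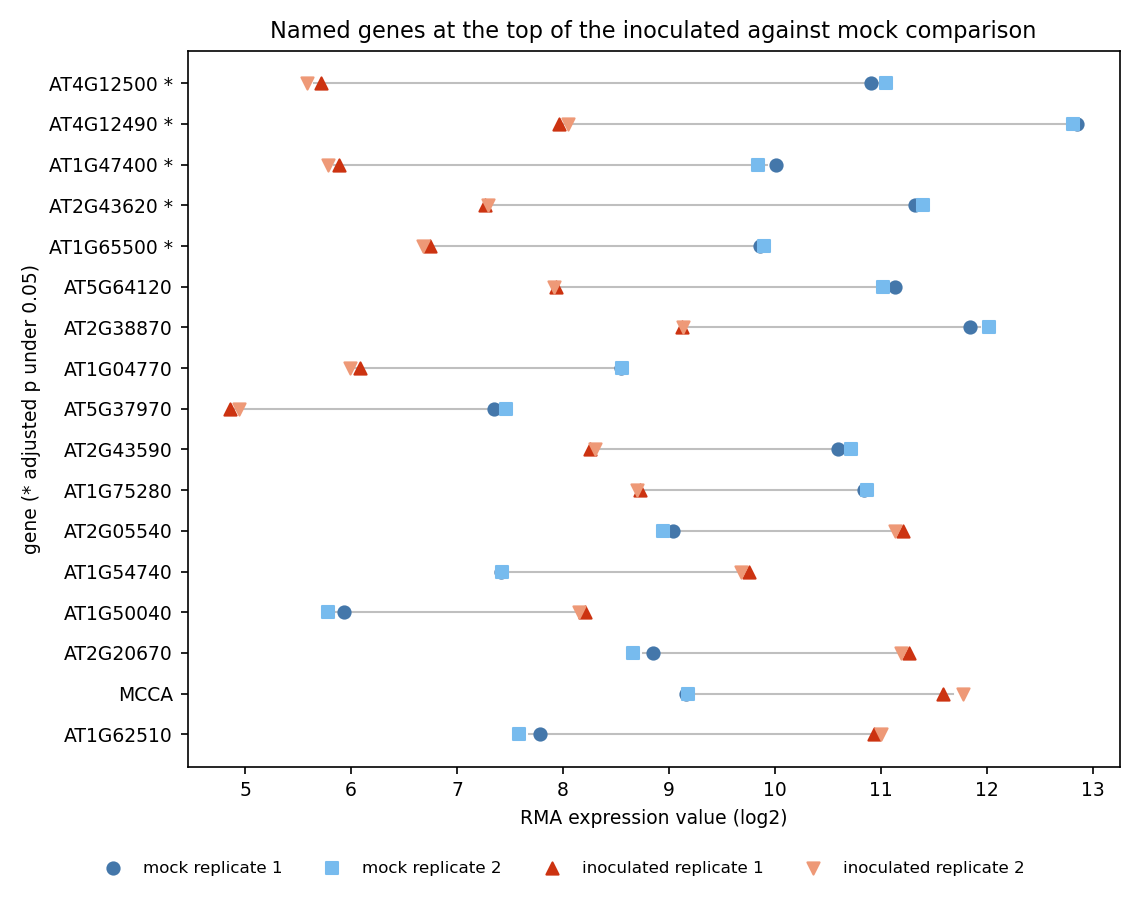
RMA log2 value (horizontal axis) of each named gene (vertical axis) on each of the 4 arrays, with a line between the group means. An asterisk marks an adjusted p under 0.05; AT4G12500 lies near 10.97 in mock and 5.65 in inoculated leaf.

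Of the 14 gene lists tested, camera called 1 higher and 2 lower in inoculated leaf. The photosynthesis list, with 8 of its 43 genes measured, rose, with all 8 higher and a median difference of 0.28 (adjusted p = 0.00202, and 0.650 with an estimated correlation). Adjusted over the list alone, 3 members were higher, against 0 over all genes: PSAN of photosystem I (0.90 ± 0.142 SE), and PRK (0.67 ± 0.148 SE) and SBPASE (0.42 ± 0.0985 SE) of the Calvin cycle. RCA, the Rubisco activase gene, differed by 0.28. The list's adjusted p was 0.121 without mock replicate 1 and 0.00901 without mock replicate 2.

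The jasmonate list, with 3 of its 26 genes measured, fell, with all 3 lower and a median of -1.27 (adjusted p = 0.00524, and 0.650 with an estimated correlation). The result covers these 3 genes and not the rest of jasmonate synthesis and response. Adjusted over the list alone, 2 were lower, against 0 over all genes: the defensin gene PDF1.2 (-1.46 ± 0.131 SE) and the thionin gene THI2.1 (-1.27 ± 0.155 SE). JMT, the jasmonate methyltransferase gene, differed by -0.55, with -0.98 without mock replicate 1 and -0.12 without mock replicate 2. The adjusted p of this list was 0.121 without mock replicate 1 and 0.00901 without mock replicate 2.

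The low oxygen list, with 7 of its 18 genes measured, fell, with 5 of the 7 lower and a median of -0.63 (adjusted p = 0.00524, and 0.759 with an estimated correlation). Adjusted over the list alone, 4 were lower, against 0 over all genes: AT4G10270 (-1.77 ± 0.107 SE), the lactate dehydrogenase gene AT4G17260 (-0.86 ± 0.109 SE), AT3G03270 (-0.81 ± 0.123 SE) and AT3G10040 (-0.63 ± 0.103 SE). Without mock replicate 1 the adjusted p was 0.456, and without mock replicate 2 it was 0.000425. None of the 3 called lists passed with an estimated correlation, which was -0.080 for photosynthesis, 0.13 for jasmonate and 0.72 for low oxygen. For photosynthesis it lay below the preset 0.01, so its higher p is not a sign of correlated members. By fry, which tests whether members move one way without comparing them with other genes, these 3 lists, touch (adjusted p = 0.0337) and abscisic acid (adjusted p = 0.0190) were called.

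The other 11 lists were not called. In touch and cell wall loosening (6 members, median -0.62, adjusted p = 0.0688) the expansin genes EXPA8 (-1.76) and EXPA4 (-0.79) were lower adjusted over the list alone, against 0 over all genes, while XTH16 differed by -0.48 (-0.052 without mock replicate 1, -0.91 without mock replicate 2) and AT1G76640 by -0.76 (-1.68 and 0.16). The list's median was -0.40 and its adjusted p 0.0382 without mock replicate 2, and its adjusted p was 0.0192 without inoculated replicate 1 and 0.0380 without inoculated replicate 2. In abscisic acid, dehydration and cold (3 members, median -0.80, adjusted p = 0.335) COR15A (-1.22) was lower adjusted over the list alone, and COR15B, at the list median, differed by -0.80 (-0.50 without mock replicate 1, -1.10 without mock replicate 2) and COR47 by 0.23. No member of the 8 lists that follow passed over all genes or adjusted over the list alone.

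For pattern-triggered immunity (7 members, median 0.09, adjusted p = 0.525) WRKY22 was 2.29-fold higher by value, and on the log2 scale BIK1 differed by 0.35, STZ by 0.21 and PUB23 by -0.36. For salicylic acid (3 members, median 0.36, adjusted p = 0.730) AT5G52810 differed by 1.02, GRX480 by 0.36 and SAG101 by -0.25. For auxin response (8 members, median -0.12, adjusted p = 0.559) LBD16 differed by -0.76, IAA20 by -0.38, IAA29 by -0.27 and LBD29 by -0.23. For phenylpropanoids and flavonoids (5 members, median -0.13, adjusted p = 0.389) UF3GT differed by -0.28, DFR by -0.27, AT5MAT by -0.13 and UGT78D2 by -0.12. For oxidative stress (3 members, median -0.24, adjusted p = 0.646) AT2G21640 differed by 0.35, GR1 by -0.26 and GSTU25 by -0.24. For Agrobacterium host factors (3 members, median 0.03, adjusted p = 0.730) MYBC1 differed by 0.30, ATLIG4 by 0.03 and AT4G32700 by 0.02. The heat shock list (4 members, median -0.04, adjusted p = 0.730) changed sign under 2 scalings, as did the reference genes (5 members, median 0.04, adjusted p = 0.730). The heat shock members were AT5G48570 (-0.12), AT5G37670 (-0.09), AT2G29500 (0.03) and ATHSP22.0 (0.02), and the 4 reference genes with the smallest p were GAPC2 (-0.30), AT2G28390 (0.34), AT4G26410 (0.14) and AT4G34270 (0.04). Several of these values rested on 1 mock array: without mock replicate 1 and without mock replicate 2, AT5G52810 differed by 1.81 and 0.23, SAG101 by -0.48 and -0.018, GRX480 by 1.105 and -0.38, LBD16 by -1.57 and 0.056, IAA20 by -0.86 and 0.096, BIK1 by 0.75 and -0.047, MYBC1 by 0.66 and -0.072, AT2G21640 by 0.74 and -0.033, GSTU25 by -0.48 and -0.0028, PUB23 by -0.17 and -0.55, DFR by -0.47 and -0.077, UF3GT by -0.52 and -0.043, LBD29 by -0.55 and 0.10 and AT2G28390 by 0.65 and 0.034. The list medians without mock replicate 1 and without mock replicate 2 were 0.22 and -0.047 for pattern-triggered immunity, 1.105 and -0.018 for salicylic acid, -0.12 and -0.014 for auxin response, -0.16 and -0.077 for phenylpropanoids, -0.23 and -0.033 for oxidative stress, 0.17 and -0.072 for host factors, -0.079 and -0.024 for heat shock and 0.030 and 0.034 for reference genes.

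**Figure D2:**
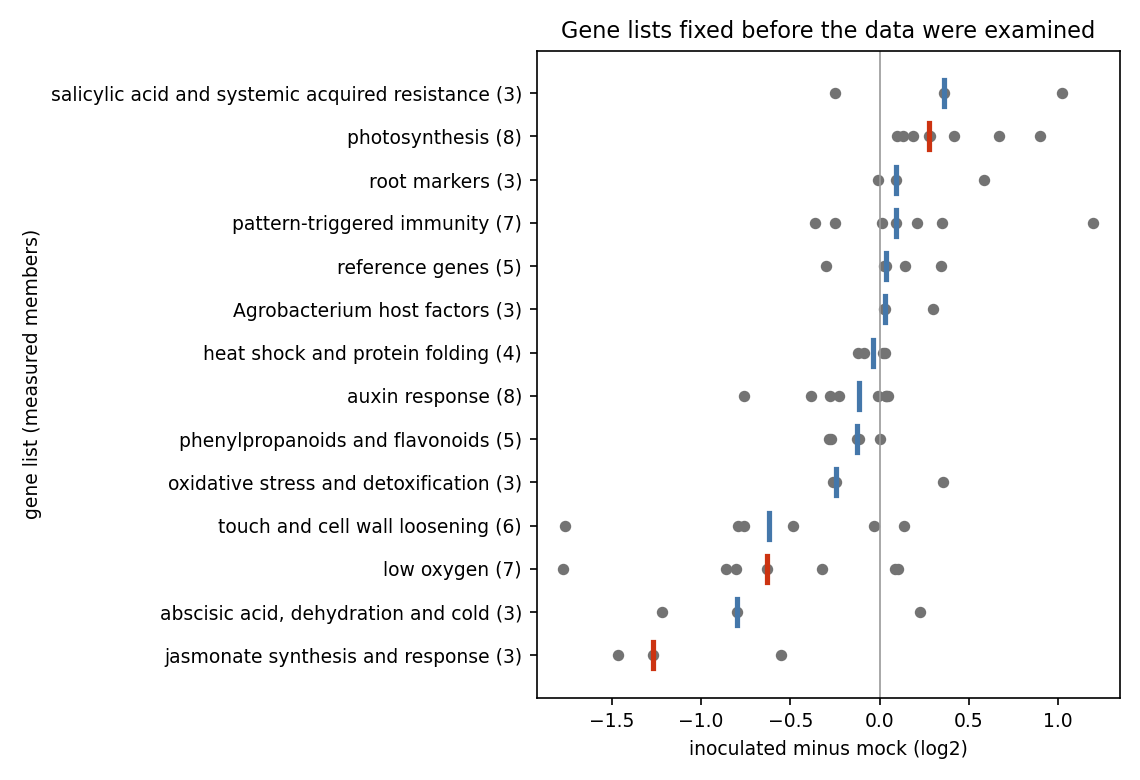
Difference between inoculated and mock leaf (log2, horizontal axis) of each measured member (grey points) of the 14 gene lists tested (vertical axis, members in brackets), with the list median as a bar, red where camera called the list. The jasmonate median lies at -1.27 and the photosynthesis median at 0.28; the medians of heat shock and of reference genes change sign under 2 scalings.

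A further 11 lists had 1 or 2 measured members and were not tested as lists. For iron homeostasis, BHLH101, a transcription factor of the iron deficiency response, differed by -1.90 ± 0.129 SE (adjusted p = 0.0585; 0.000542 adjusted over the list alone) and PYE by -0.60. EXO of the sugar and dark starvation list differed by 0.99 (0.0013 adjusted over the list alone), the guard cell marker AT1G22690 by 0.88 (0.00326) and UGT74B1 of the indole glucosinolate list by -0.80 (0.00528), against adjusted p-values over all genes of 0.0924, 0.0960 and 0.152. Not past the test either way was FMA (0.50), the other measured guard cell marker. Nor were BCAT4 (1.73) and AT2G31790 (-0.20) of aliphatic glucosinolates or GI of the circadian clock (1.26, with mock values of 7.81 and 6.53). ARR15 (-0.49) and RR16 (-0.05) of cytokinin response and EIN3 of ethylene response (0.03) did not pass either. The same held for AUR1 (-0.47) and PRL (0.32) of the cell cycle, the ribosomal protein genes AT3G09630 (-0.14) and AT2G19730 (-0.12) and the meristem marker CLV3 (0.17). Without mock replicate 1 and without mock replicate 2, BCAT4 differed by 2.73 and 0.73, FMA by 0.83 and 0.18, GI by 1.91 and 0.62, PYE by -0.16 and -1.04, ARR15 by -0.98 and -0.014, AT2G31790 by 0.18 and -0.58, AUR1 by -0.65 and -0.29 and PRL by 0.74 and -0.11. Phosphate starvation, nitrate response, leaf senescence, epidermis and vascular markers had no measured member. Over the 85 measured members, 17 passed adjusted over the list alone (6 higher, 11 lower), against 0 over all genes. Leaving out 1 array moved 56 of the 85 differences by over 1.5 times or changed their sign, and 0 of those 17. The 17 were picked by a small p on the same arrays, which needs replicates that lie close together. Their stability is therefore no separate support.

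Photosynthesis genes were abundant on every array, from 10.92 to 13.94, with array medians of 13.19 and 13.22 in mock and 13.45 and 13.46 in inoculated leaf. The root hair markers EXPA7 (5.26, 5.12, 5.19 and 5.18 in mock replicates 1 and 2 and inoculated replicates 1 and 2) and EXPA18 (5.64, 5.44, 5.61 and 5.66) read low. PYK10, a root-abundant beta-glucosidase, averaged 9.07 in mock and 9.66 in inoculated leaf, a difference of 0.58 ± 0.115 SE (adjusted p = 0.188; 0.0293 adjusted over the list alone). The root marker list was not called (3 members, median 0.09, adjusted p = 0.377; medians of 0.19 without mock replicate 1 and -0.0018 without mock replicate 2).

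Of the 16 actin, GAPDH and ubiquitin control probe sets, 15 were lower in inoculated leaf as deposited and under each scaling, by values from -0.78 to -0.23 as deposited and from -0.81 to -0.17 over deposited values and scalings; the exception, an actin 5' probe set, changed sign between scalings. The 3' minus 5' difference of the control pairs averaged 1.45 in mock and 1.36 in inoculated leaf. The groups differed by -0.0905 ± 0.113 (SE over 6 pairs), less than that error, with pairs from -0.60 (actin) to 0.21 (ubiquitin). The pairs are repeated readings of actin, GAPDH and ubiquitin, so that error treats them as more independent than they are.

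The arrays were not equally alike. Across probe sets, which are not independent replicates, the inoculated arrays correlated at r = 0.999 and differed by an SD of 0.0877, with 0 probe sets more than 1 log2 apart. The mock arrays correlated at r = 0.931, with 3178 probe sets more than 1 log2 apart. Mock replicate 2 had an SD across probe sets of 1.67, against 1.82 in mock replicate 1 and 1.83 in both inoculated arrays. It lay above the others by 0.62 at a mean level of 4 to 5 and differed from them by -0.44 at a level of 7 to 8.

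**Figure D3:**
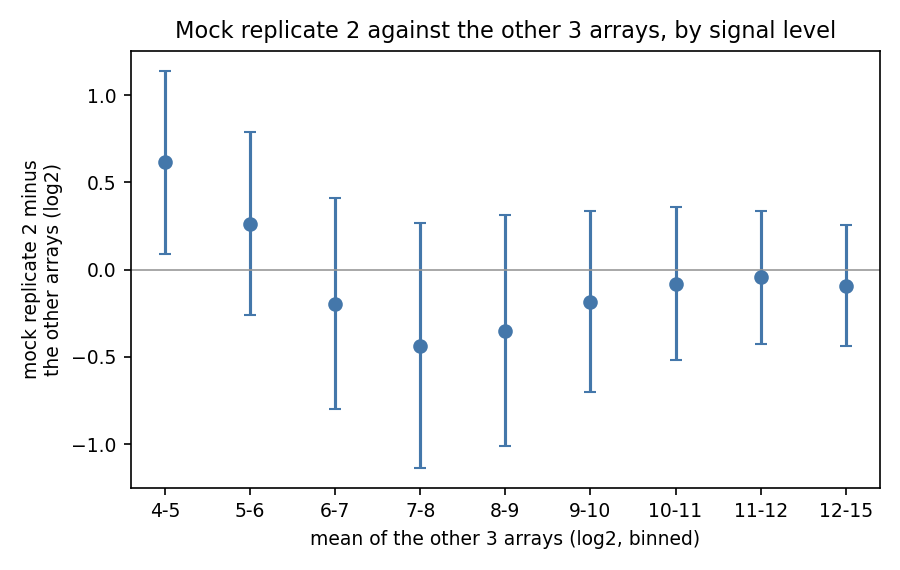
Mean difference of mock replicate 2 from the mean of the other 3 arrays (log2, vertical axis, bars 1 SD across probe sets) by the level of those arrays (log2, horizontal axis). The difference runs from 0.62 at a level of 4 to 5 to -0.44 at 7 to 8.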

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

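All tests in this part were chosen only after the results they address had been seen. With 2 arrays per group, a test for a single deviating array was not run.

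Mock replicate 2 stood apart from the other arrays, with an own SD of 0.650 against 0.140 for mock replicate 1 and 0.0620 for each inoculated array. The tables argue, only weakly, against a different state of the leaf RNA alone. Over 45 control probe sets without a plant target, mock replicate 2 deviated from the inoculated mean with an SD of 0.646 and mock replicate 1 with 0.197, a ratio of 3.28 (95% bootstrap interval 2.14 to 4.62, 2000 draws). These probe sets are repeated readings of a few bacterial and phage transcripts. The interval treats them as independent and so is likely too narrow. A distortion of signal on the array itself is a candidate explanation, since it needs that spread of 0.646 in probe sets with no leaf target. The labels name no difference between the mock samples, so no biological explanation was tested.

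Inoculated and mock leaf differed, and the tables argue against the deviation of mock replicate 2 as the whole source. Over all probe sets, the differences of the inoculated mean from mock replicate 1 and from mock replicate 2 shared a covariance of 0.125 (0.124 within levels of signal), to which a deviation of mock replicate 2 alone adds nothing; it was 65.1 times the error variance of the inoculated mean (95% bootstrap interval 60.6 to 69.9). That error is between 2 nearly identical arrays and may be technical alone, whereas limma's test, whose spread includes the mock pair, called 9 probe sets. The interval treats probe sets as independent and holds no spread between plants. Anything peculiar to the inoculated pair also adds to that covariance. A mean 3' minus 5' shift of 0.5 log2 was set as what RNA degradation would need. The mean difference was -0.0905 ± 0.113 SE over 6 pairs, of which 3 were lower in inoculated leaf. The pairs are a first and a second version of actin, GAPDH and ubiquitin, so that SE treats repeated readings as independent. They ran from -0.60 (first actin pair) to 0.21 (first ubiquitin pair). The mean lay short of that shift, but with so few genes the test is weak, and a smaller shift stays open. The inoculation itself stays open as the biological explanation. The labels name no batch, so a batch that follows the groups cannot be told apart from it.

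The 2 inoculated arrays were nearly identical, with an SD of their difference of 0.0877. One labelled target on both arrays is argued against only weakly. The poly-A spikes, added before labelling, differed by a mean of 0.161 ± 0.0235 SE and were higher in inoculated replicate 2 for 23 of 24 probe sets. The hybridisation controls, added after labelling, differed by -0.0143 ± 0.0160 SE and mostly read at higher levels. Both sets are repeated readings of a few transcripts (dap, lys, phe and thr for the spikes). These errors, the count of 23 and the interval that follows treat such readings as independent. One leaf RNA extract labelled 2 times cannot be told apart from 2 extracts, because the SD over 12323 leaf probe sets of like level (0.0984) was 0.854 times that of the spikes (0.115), with a 95% bootstrap interval of 0.704 to 1.16. If one extract was used, the inoculated group may hold 1 biological sample. Averaging these arrays keeps the same differences and leaves 1 residual degree of freedom, with the residual spread taken from the mock pair alone. The loss of calls in that fit says nothing of the size of the differences, and its cause was not tested. The labels call the inoculated arrays biological replicates, which stays open.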

How the results depend on the processing

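Array weights and the averaging of the inoculated arrays were chosen after seeing the data; the other alternatives were planned. The 9 called probe sets were all called again with an intensity trend, minimum mean log2 values of 5 and 7, repeated quantile normalisation, cyclic loess, array weights and without cross-hybridising probe sets. Of the 9, 6 were called with a robust prior, 7 with median centring and 0 with a replicate block. Fits with 1 array or 1 averaged sample in a group are left out of this tally, because their residual spread comes from the other group alone. The count of 9 moved to 741 with an intensity trend (352 higher, 389 lower), 826 at a minimum mean log2 value of 7, 45 with repeated quantile normalisation, 154 with cyclic loess, 434 at an adjusted p under 0.10, 2783 with array weights and 0 with the inoculated arrays averaged (568 at an unadjusted p under 0.05). The count over the arrays left out in turn ran from 0 to 17356. The count of 3 called lists was 0 with an estimated correlation and 5 with fry, and ran from 0 to 4 over the arrays left out in turn. Averaging takes the residual spread from the mock pair alone. For none of these moves was the cause tested. The adjusted p of AT1G47400 and AT1G65500 was 0.0572 with a robust prior, and that of AT1G65500 was 0.0545 with median centring. Signal near background limits differences at low levels, the folds of strongly lowered transcripts included, and mock replicate 2 lay 0.62 above the others at a level of 4 to 5.

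The labels' replicate numbers do not show that the arrays pair, and deviations of same-numbered arrays correlated at -0.0862 across probe sets. With a replicate block, limma called 0 probe sets (1715 at an unadjusted p under 0.05, lowest adjusted p 0.384) and 4 lists.

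Over all named genes and alternatives, 938 values kept their direction and side of the threshold, 214 passed it, 23 no longer did and 50 changed sign. For lists these counts were 148, 7, 6 and 7, and they do not cover every sign change of a list median given below. For those that changed sign the cause was not tested. With repeated quantile normalisation the difference was -0.095 for ATLIG4, -0.021 for EIN3, 0.069 for AT5G48570, 0.12 for AT5G37670, 0.073 for AT5MAT, -0.076 for AT4G34270 and 0.14 for EXPA7, and the medians of heat shock and of reference genes were 0.13 and -0.065. With cyclic loess it was -0.11 for ATLIG4, -0.026 for EIN3, 0.032 for AT5G48570, 0.028 for AT5G37670, 0.0082 for AT5MAT, -0.12 for AT4G34270 and 0.16 for EXPA7, and the medians of heat shock and of reference genes were 0.10 and -0.053. With median centring it was -0.0035 for ATHSP22.0. With array weights it was -0.039 for MYBC1, -0.12 for AT4G32700, 0.054 for IAA20, 0.072 for LBD29, -0.068 for PRL, 0.12 for RR16, -0.011 for BIK1, -0.32 for GRX480 and 0.078 for AT1G76640. The weighted medians were -0.011 for pattern-triggered immunity, -0.039 for salicylic acid and -0.039 for Agrobacterium host factors.

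With each array left out in turn, differences ran from -0.092 to 0.16 for ATLIG4, -0.58 to 0.18 for AT2G31790, -0.12 to 0.19 for EIN3, -0.26 to 0.081 for AT5G37670, -0.16 to 0.23 for AT2G29500, -0.093 to 0.13 for ATHSP22.0, -0.24 to 0.010 for UGT78D2, -0.051 to 0.12 for AT4G34270, -0.080 to 0.067 for EXPA7, -0.072 to 0.66 for MYBC1 and -0.13 to 0.17 for AT4G32700. They ran from -1.57 to 0.056 for LBD16, -0.86 to 0.096 for IAA20, -0.55 to 0.10 for LBD29, -0.11 to 0.74 for PRL, -0.24 to 0.14 for RR16, -0.033 to 0.74 for AT2G21640, -0.047 to 0.75 for BIK1, -0.0018 to 0.19 for EXPA18, -0.38 to 1.105 for GRX480 and -1.68 to 0.16 for AT1G76640. List medians ran from -0.072 to 0.17 for Agrobacterium host factors, -0.047 to 0.22 for pattern-triggered immunity, -0.018 to 1.105 for salicylic acid and -0.0018 to 0.19 for root markers.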

Other observations

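All tests in this part were chosen after the data had been seen: 29 families before the fit, 4 wider lists after it. Beyond the lists fixed in advance, 1 family of secreted peptides was lower and 2 families were higher in inoculated leaf. Plant defensins and low-molecular-weight cysteine-rich proteins fell (12 of 13 members lower, median -0.53, adjusted p = 0.000988; adjusted p = 0.620 with an estimated correlation), and 4 were lower adjusted over the list alone, against 0 over all genes: PDF1.2 (-1.46), which is also in the jasmonate list, PDF1.4 (-1.39), PDF1.2b (-0.93) and LCR66 (-0.90). Without mock replicate 2 the defensin median was -0.13 (adjusted p = 0.0121). Probe sets of plastid-encoded genes read higher (54 of 69 higher, median 0.23, adjusted p = 0.000218, and 0.620 with an estimated correlation), with 0 members passing adjusted over the list alone. Of these, psbD differed by 0.82 and psbA by 0.71. Whether the 3' IVT labelling reads plastid transcripts as it reads nuclear ones was not tested. These values are therefore signal and not shown to be transcript levels. Autophagy genes rose (7 of 8 higher, median 0.27, adjusted p = 0.0136; adjusted p = 0.620 with an estimated correlation), and ATG8E (0.84), ATG8H (0.78) and ATG8B (0.54) were higher adjusted over the list alone, against 0 over all genes. Without mock replicate 2 the plastid list had a median of 0.14 and an adjusted p of 0.0697, and the autophagy list an adjusted p of 0.111, so neither was called. The other 26 families were not called by camera, with adjusted p-values from 0.127 to 0.989. By fry, which does not compare a family with other genes, 6 families passed: the defensins (adjusted p = 0.0136), lower IQ-domain proteins (0.00460), RALF-like peptides (0.00865), cytochromes P450 (0.0292) and expansins (0.0389), and higher SEC and VPS proteins (0.0389). Their medians as measured and without mock replicate 2 were -0.14 and -0.12 for IQ-domain proteins, -0.19 and -0.024 for RALF-like peptides, -0.091 and -0.034 for cytochromes P450, -0.22 and -0.063 for expansins and 0.10 and 0.065 for SEC and VPS proteins. The plastid-encoded (0.245) and autophagy genes (0.0853) did not pass by fry.

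Among genes chosen after their values were seen, IVD (2.46), MCCB (1.48) and AT4G33150 (1.89), which act in branched-chain amino acid and lysine breakdown, were higher by value next to MCCA (2.51). A hypothesis was that the pathway beyond these genes may be higher. The other 8 measured members rose as a list (6 higher, median 0.89, adjusted p = 0.00207; adjusted p = 0.153 with an estimated correlation). Without mock replicate 2 the median was 0.45 (adjusted p = 0.00554). Among these members 4 passed adjusted over the list alone, against 0 over all genes: ETFQO (2.07), ALDH6B2 (1.58), ETFBETA (1.03) and AT2G26800 (0.45).

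A further hypothesis was that sugar starvation genes may be higher. The wider list rose (6 of 6 higher, by 0.42 to 3.51, adjusted p = 1.04e-06; adjusted p = 0.0736 with an estimated correlation), and all 6 passed adjusted over the list alone, against 0 over all genes, with ATL8 at 3.51, AT5G24490 at 1.19 and AKINBETA1, a subunit of the SnRK1 kinase complex, at 1.15.

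Another hypothesis was that families of secreted defence proteins may be lower beyond the genes seen in the ranking. Chitinases, class III peroxidases, berberine bridge enzymes and AZI1-like proteins fell as a list (15 of 18 lower, median -0.38, adjusted p = 8.83e-05; adjusted p = 0.0736 with an estimated correlation). Adjusted over the list alone 3 were lower, against 0 over all genes: PRX52 (-1.80), AT1G26380 (-1.20) and AT1G26410 (-1.17).

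The last hypothesis was lower iron deficiency genes, and the wider list had only 2 measured members, with a median of -0.405. AT3G56360 (-1.07) was lower adjusted over the list alone (adjusted p = 0.00177), against an adjusted p of 0.0812 over all genes, and differed by -1.10 to -1.04 with each array left out. AT3G07720 differed by 0.26, and by -0.19 without mock replicate 2. A lower list cannot be told apart from a lower single gene, because 2 members are too few for a list test.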
